A study of Homo sapiens and Mus musculus with 10 samples.

How the data were processed

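RNA of 2 established lines was analysed in 10 libraries, 7 HEK293T and 3 N2a libraries. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the TruSeq Ribo Profile kit. The submitters' processing notes name cutadapt, FastQC, Bowtie2, bedtools and the builds hg19 and mm10, without versions or settings. Counting rule, annotation release and use of strand are not given in the sources used here. The 3 deposited tables hold the authors' raw read counts per RefSeq transcript, whole numbers that are not normalized, with 16120 rows for the HEK293T stress set, 11976 for the genotype set (lowest row sum 75, so rare transcripts were left out before deposit) and 24770 for N2a. The genotype table also holds the authors' deposited log2 ratios and p-values of deficient over WT for mock and GD. These log2 ratios equal ratios of CPM (reads scaled to library size) to within 0.00624 over 5852 rows with over 200 reads. They were read only for comparison.

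Each symbol has 1 transcript row in the HEK293T tables, so the counts are those of a transcript row and need not be gene totals. For 1122 of 11477 symbols (9.78%) the 2 tables hold different transcripts, and only the 10368 transcripts in both were tested together. A total of 21 rows had symbols turned into dates or numbers by spreadsheet software and were named by their transcript accession. N2a rows carry accessions only, and 0% of them match the reference used here, so N2a genes are not named. The reference was a RefSeq gene table on GRCh38.p14, another build than the authors' hg19. It served for names, chromosomes and gene order, and no coordinates are given. GC content was taken from GENCODE transcripts.

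Genotype and treatment came from the labels. The titles place the libraries in a stress set and a genotype set. Nothing in the labels says whether libraries came from separate cultures. No condition was repeated within a set, so p-values rest on how far the GD response differs between the 3 mock and GD pairs. They do not measure spread between repeats of a condition, and the spread they use may be technical. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the 6 HEK293T mock and GD libraries with set, genotype and treatment as terms, which leaves 2 residual degrees of freedom. It used TMM factors, the default expression filter (which removed no shared transcript) and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0192. A set of 29 gene lists was fixed before the data were examined. The 26 with 5 or more tested members were tested with limma's camera (3.58.1) at a correlation of 0.01 on log2 CPM with a prior count of 2, again with an estimated correlation, and with fry. With an estimated correlation, camera takes its p on the 2 residual degrees of freedom. That form could hardly call a list after adjustment over 26 lists, so its lack of calls decides little. Fry's p tests whether a list moves on balance in a direction and does not compare it with other genes.

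Comparisons with 1 library per condition have no p-value. A transcript counted as changed at 2-fold or more with 50 or more reads in the higher library, on TMM-scaled CPM with a prior count of 5. Folds in words are ratios of scaled reads with exact conditional 95% intervals, which cover counting error only. A list median was placed among 10000 random lists of the same size drawn within 20 bins of expression. For a transcript at 0 reads the fold is a bound against 3 counts per library that takes the other library's reads as counted, so the exact 95% lower limits are lower. Chance overlap from the shared mock library was simulated with the dispersion of the tested HEK293T libraries. This was done for N2a too, which has 1 library per condition and no dispersion of its own.

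Named genes were chosen by a rule fixed before the data were examined. For a tested comparison these are the 10 largest rises and falls with the same sign in every pair. For a comparison without a test they are the 10 highest and lowest ratios, with 5 each for the response by genotype, leaving out small RNA, histone and uncharacterised names. Added to these are up to 4 members of each list with the largest change, and UFD1, NPLOC4 and VCP. From the lists the text names called members. Some genes that the rule names are not reported here. HMOX1, RNA45SN5, the end genes of chromosome stretches and the genes in the last part were named after their values were seen.

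The scripts were tested on simulated counts with 200 changed transcripts among 10368. For the GD comparison edgeR recovered 94% of 2-fold and 100% of 4-fold changes, with 9 false among 203 calls, and DESeq2 77% and 97%. For the genotype comparison edgeR recovered 78% and 99%, with 9 false among 186 calls. The rule of size recovered 200 of 200 changes of 4-fold, with 20 false among 8969 transcripts. Planted changes of 4-fold lie well past the rule's bound of 2-fold, so this recovery was likely in advance. It does not cover changes near that bound. The recovered shares of all these runs hold for the simulated counts and need not hold for the real libraries. The list test called the shifted list and 0 others of 26, and the search for stretches found 1 stretch of 216 genes for 200 planted.

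Alternatives were other size factors, other filters, DESeq2 (1.42.0), limma-trend, other sets of libraries and thresholds, prior counts and list tests. Library depth ran from 11216493 to 19024327 reads. The comparison of HEK293T with N2a by gene name was planned and left out because N2a transcripts could not be named.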

Results

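The series measured RNA by sequencing after removal of ribosomal RNA in HEK293T, a human embryonic kidney line, and N2a, a mouse neuroblastoma line. Cells were mock-treated, deprived of glucose for 24 h (GD, described by the submitters as metabolic oxidative stress) or treated for 6 h with 300 nM thapsigargin (TG), an inhibitor of the calcium pump of the endoplasmic reticulum (ER) that causes ER stress. There were 10 libraries, 7 from HEK293T and 3 from N2a. A stress set held 1 wild-type (WT) library each of mock, GD and TG in each line. A genotype set held 1 HEK293T library each of WT mock, WT GD, UFD1s-deficient mock and UFD1s-deficient GD, so WT mock and WT GD had 2 libraries each and each other condition had 1. Reads counted on transcripts came to 16990125, 12771607 and 19024327 in the mock, GD and TG libraries of the HEK293T stress set. They came to 12379960 and 11461365 in WT mock and WT GD of the genotype set and to 13110714 and 11912659 in deficient mock and GD. The N2a libraries held 11994514, 11216493 and 11932169 for mock, GD and TG. The ribosomal precursor RNA45SN5 took 7.73% of the reads of the stress-set mock library, 10.69% of GD and 8.31% of TG. The WT mock libraries of the 2 sets differed by far more than sampling noise, with a chi-square of 73.8 per degree of freedom, against 17.0 between WT and deficient mock within the genotype set.

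UFD1 is a cofactor of the ATPase VCP (p97), with which it and NPLOC4 extract ubiquitinated proteins, and UFD1s is, per the labels, the form missing in the deficient line. The deposited tables count a UFD1 transcript in each set but not the same transcript. In the stress set, NM_001035247.2 had 10 reads in mock and 0 in GD and TG. In the genotype set, NM_005659.6 had 168 reads in WT mock, 107 in WT GD, 199 in deficient mock and 193 in deficient GD. Neither count was stated to cover the part of UFD1 that differs in the deficient line, so these reads check nothing about the genotype labels. NPLOC4 had 4566 and 3664 reads in WT mock and GD and 5373 and 4550 in the deficient libraries, and 5529, 2743 and 5004 in stress-set mock, GD and TG. VCP had 10385, 7178, 11206 and 8286 reads in the same order of genotype-set libraries and 14504, 7504 and 21758 in the stress set. Between genotypes the log2 differences were 0.21 for NPLOC4 and 0.09 for VCP, with edgeR adjusted p of 0.513 and 0.772. In GD, VCP fell by 0.33 on the log2 scale (edgeR adjusted p = 0.0262), and NPLOC4 was not called at −0.21.

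The first comparison asked which transcripts change in HEK293T cells without glucose. Among the largest rises were genes of the integrated stress response, the programme run by the kinase PERK and the transcription factors ATF4 and CHOP. DDIT3, which encodes CHOP, was higher by 4.14 on the log2 scale (SE 0.502, n = 3 mock and GD pairs, edgeR adjusted p = 0.0009975), with 4, 16 and 10 reads in the mock libraries and 217, 98 and 136 in GD. TRIB3, a pseudokinase induced by CHOP, rose by 2.97 (SE 0.264, edgeR adjusted p = 0.0003282), and PPP1R15A, the phosphatase subunit GADD34, rose by 2.96 (SE 0.0955, edgeR adjusted p = 7.167e-07). GDF15, a secreted stress cytokine, rose by 3.34 (5.24 in the stress set, 2.35 in genotype-set WT and 1.43 in deficient cells) and INHBE by 2.51 (3.60, 1.08 and 1.63). In the genotype set alone their changes were 2.15 and 1.65. Of the 31 tested members of the list of integrated stress response targets, 23 rose and 0 fell, also when adjusted over the list alone, and the median log2 change was 1.11. The medians were 1.29 in the stress set, 1.08 in genotype-set WT and 0.80 in deficient cells. The list was called by camera with a preset correlation (limma, adjusted p = 1.186e-16) and not with an estimated correlation (adjusted p = 0.386). The second form rests on 2 residual degrees of freedom and could hardly call any list after adjustment.

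Genes of protein folding and degradation in the ER, targets of ATF6 and XBP1, rose with them. HSPA5, the main ER chaperone BiP, was higher by 2.45 (SE 0.235), HERPUD1 by 2.26, DNAJB9 by 1.65 and XBP1 by 1.61. In all, 22 of 29 tested members rose and 0 fell, also when adjusted over the list alone. The median was 0.80, with 1.26 in the stress set, 0.64 in genotype-set WT and 0.70 in deficient cells (camera adjusted p = 1.309e-12 in limma, adjusted p = 0.516 with an estimated correlation). Among 15 tested NRF2 antioxidant genes, 5 rose and 0 fell, also over the list alone, led by OSGIN1 at 2.49 and the cystine transporter SLC7A11 at 2.28, which the integrated stress response list also holds. The ferritin chains FTL and FTH1 rose by 0.86 and 0.84 (camera adjusted p = 0.003416 in limma, adjusted p = 0.386 with an estimated correlation). HMOX1, another member, was not called at 0.76, with 3.09 in the stress set, −0.77 in genotype-set WT and −0.08 in deficient cells.

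**Figure D1:**
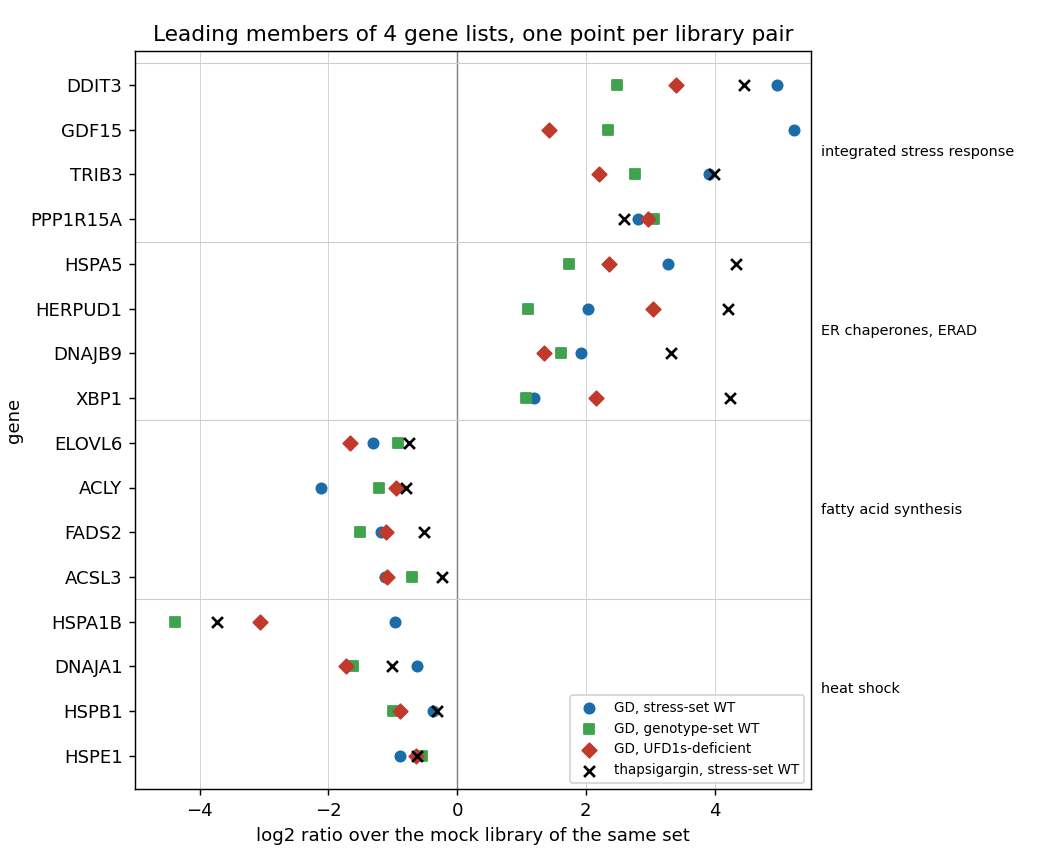
Log2 ratio of treated over mock reads for leading members of 4 gene lists, with 1 point per library pair (x axis, log2 ratio with a prior count of 5; y axis, genes grouped by list). All 3 GD pairs lie above 0 for the integrated stress response and ER genes and below 0 for the fatty acid synthesis and heat shock genes shown, where HSPA1B lies at −0.96, −4.38 and −3.07 in stress-set WT, genotype-set WT and deficient cells.

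Lipid synthesis genes moved the other way. Of 9 tested genes of fatty acid synthesis, 6 fell and 0 rose, with 7 falling when adjusted over the list alone. ELOVL6, a fatty acid elongase, changed by −1.46, ACLY, which makes cytosolic acetyl-CoA from citrate, by −1.45, the desaturase FADS2 by −1.26 and ACSL3 by −1.02. The median was −0.94 (camera adjusted p = 0.0001142 in limma, adjusted p = 0.386 with an estimated correlation, fry adjusted p = 0.0312). Of 17 cholesterol genes, 9 fell and 0 rose, also over the list alone, including IDI1 at −1.13 and TM7SF2 at −0.99 (median −0.58; camera adjusted p = 0.0001493 in limma, adjusted p = 0.516 with an estimated correlation). Heat shock genes fell as well, 8 of 12 with 0 rising, also over the list alone. HSPA1B changed by −2.81, the HSP70 co-chaperone DNAJA1 by −1.32, HSPB1 by −0.77 and HSPE1 by −0.69 (median −0.43; camera adjusted p = 0.0001142 in limma, adjusted p = 0.386 with an estimated correlation). In the stress set alone, 3 of 14 measured heat shock genes were at least 2-fold higher and 0 lower in GD. HSPA1B is nearly identical to HSPA1A, and the counts may split reads between them.

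Cytosolic ribosomal protein transcripts rose by small amounts, 19 of 52 with 0 falling and 29 when adjusted over the list alone, with a median of 0.26. RPS3 was higher by 1.67, RPS24 by 1.26 and RPL12 by 0.66 (camera adjusted p = 1.902e-10 in limma, adjusted p = 0.386 with an estimated correlation, fry adjusted p = 0.0196). Among small structural RNAs and their host transcripts, listed as a sign of library quality, 6 of 8 rose and 0 fell (7 over the list alone), including GAS5 at 1.27 and SNHG1 at 0.87 (camera adjusted p = 1.461e-05 in limma, adjusted p = 0.579 with an estimated correlation). Of 7 nuclear-retained RNAs, MALAT1 at 0.82 and NEAT1 at 0.61 rose and 0 fell, also over the list alone, with list medians of 0.46 in the stress set, 0.07 in genotype-set WT and 0.04 in deficient cells (camera adjusted p = 0.0498 in limma, adjusted p = 0.626 with an estimated correlation). Of 16 replication-dependent histone transcripts, 5 fell and 0 rose, also over the list alone, with HIST1H3A at −1.62 and list medians of −0.61 in the stress set, −0.13 in genotype-set WT and −0.12 in deficient cells. Their camera adjusted p was 0.002957 in limma, with an adjusted p of 0.626 with an estimated correlation, and histone genes share sequence. The p97 and proteasome list had 6 falls and 1 rise in 33 (9 and 2 over the list alone), with PSMD11 at −1.24, PSMA3 at −1.05 and the VCP cofactor FAF1 at 0.45 (camera adjusted p = 0.007149 in limma, adjusted p = 0.626 with an estimated correlation). Its median was −0.44 in the stress set, −0.07 in genotype-set WT and −0.07 in deficient cells, and the list was not called without the stress set.

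The other lists were not called by camera in the 6 libraries. In glycolysis, 5 of 16 genes rose and 2 fell, also over the list alone, with the hexokinase HK2 at 0.82, the glucose transporter SLC2A1 at 0.76, ENO2 at 0.64 and PGAM1 at −0.86. Of 3 measured MondoA and ChREBP targets, ARRDC4 alone passed, at −0.65. Of 22 immediate early genes, 7 rose and 2 fell (7 and 3 over the list alone), led by CYR61 at 1.71, KLF4 at 1.67 and EGR1 at 1.32, and camera called this list higher in the genotype set alone. DNA replication had 4 rises and 9 falls in 26 (4 and 11 over the list alone), with RFC5 at 1.20, CDT1 at 1.09 and FEN1 at −0.74. In G2 and M, 3 of 25 fell and 0 rose (1 and 0 over the list alone), including KIF20A at −0.67 and CCNB1 at −0.36, and the list median was −0.53 in the stress set against 0.11 in genotype-set WT. Autophagy and lysosome genes gave 7 rises and 2 falls in 26 (8 and 3 over the list alone), with WIPI1 at 1.09, GABARAPL1 at 0.87 and SESN3 at −0.85. Of 10 mitochondrial stress genes, 4 rose and 1 fell (4 and 2 over the list alone), including LONP1 at 0.70 and HSPA9 at 0.55. Nuclear-encoded respiratory chain genes had 3 falls (COX7B, CYCS and NDUFA4) and 0 rises in 41, also over the list alone, and 0 mitochondrially encoded genes were tested. For p53 targets, 3 of 11 rose and 1 fell, also over the list alone, with GADD45A at 2.36, PLK3 at 0.92, CCNG1 at 0.63 and BTG2 at −1.09. HRK, at 1.14, was the single called member of 7 apoptosis genes (0 over the list alone). Hypoxia genes had 3 rises and 1 fall in 11, also over the list alone, with BHLHE40 at 1.42 and EGLN3 at −1.65. Among interferon and NF-kB genes 2 of 13 rose and 0 fell (2 and 1 over the list alone), RELB at 2.22 and the chemokine CXCL8 at 1.99. Ribosome biogenesis had 2 falls and 0 rises in 23 (1 and 0 over the list alone), and fatty acid oxidation 1 fall in 16, CPT2 at −0.58. Extracellular matrix genes had 2 rises and 3 falls in 14 (3 and 3 over the list alone), with TGFBI at 1.95, LUM at −1.85, COL3A1 at −1.28 and COL1A1 at −1.07. Of 8 neuronal markers 3 fell and 0 rose, also over the list alone, ISL1 at −1.24, HAND2 at −1.15 and NEFL at −0.72, and of 3 epithelial markers KRT19 fell, at −0.59. For p53 targets and hypoxia the median was below 0 (−0.06 and −0.10) while the mean was above it (0.18 and 0.16), and for ribosome biogenesis the median was −0.02 while camera's direction was up.

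Outside the lists, KLHDC7B had 0 reads in all 3 mock libraries and 197, 66 and 63 in GD, at least 95.7-fold higher in the stress set, 25.2-fold in genotype-set WT and 24.2-fold in deficient cells against a floor of 3 counts per library. The exact 95% lower limits, which also cover counting error in GD, are 77.1, 19.9 and 19.1. NEMP1 rose by 2.97, the snoRNA host SNHG7 by 2.85, SLC7A11-AS1, antisense to SLC7A11, by 2.67 and KRT17 by 2.63. The strand of the counts is not stated, so reads of SLC7A11-AS1 and SLC7A11 cannot be told apart where they overlap. The largest falls were ITGA8 (−3.71), PITX3 (−3.03), CAVIN2 (−2.94), HES5 (−2.65), NDST4 (−2.62), IGFBP5 (−2.52, SE 0.212, edgeR adjusted p = 0.0002677), SLITRK3 (−2.44), EOMES (−2.42) and SERTM1 (−2.41), with under 100 reads in each mock library except for IGFBP5, which had 566 to 935.

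In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2164 of 10368 transcripts, 1011 higher (46.7%) and 1153 lower, of which 422 differed at least 2-fold, 173 higher and 249 lower. Of the 2164, 2159 had the same sign in all 3 pairs. With library totals alone the split was 683 higher (30.9%) and 1526 lower of 2209, while RLE size factors gave 1147 higher (52.0%) and 1058 lower and DESeq2 1018 higher (51.5%) and 958 lower. The stress-set pair alone, by a rule of at least 2-fold and 50 reads in the higher library, gave 650 of 8904 transcripts, 332 higher and 318 lower. The count of tested calls depended on the libraries entered. It was 4040 in the 4 libraries of the genotype set, 490 in the 4 WT libraries and 23 with treatment as the only term. It was 494 without deficient GD, 504 without deficient mock, 1147 and 1189 without WT GD and WT mock of the genotype set, and 3806 and 4039 without WT mock and WT GD of the stress set. Camera called 11 of 26 lists with 5 or more tested members, fry called 2, and 0 were called with an estimated correlation, where the lowest adjusted p was 0.386 and ribosomal proteins, heat shock and fatty acid synthesis had unadjusted p of 0.0242, 0.0474 and 0.0486 in limma. Heat shock and fatty acid synthesis had estimated correlations of −0.07 and −0.12, below the preset 0.01. For these 2 lists correlation thus did not undo the calls, and the few degrees of freedom limit this form. Other called lists had estimates of −0.03 (NRF2), 0.01 (ribosomal proteins), 0.12 (cholesterol), 0.19 (integrated stress response) and 0.45 (ER genes). For p97 and proteasome, histones, small structural RNAs and nuclear-retained RNAs they were 0.54, 0.70, 0.82 and 0.91. In this form the p97, histone and nuclear-retained lists had unadjusted p of 0.51, 0.41 and 0.45 in limma. At such correlations the degrees of freedom alone need not explain the lost calls. Across transcripts, which are not independent replicates, the GD ratio of the stress set correlated with that of genotype-set WT at r = 0.466, and WT with deficient cells at r = 0.667. Besides GDF15 and INHBE, genes whose changes shrank by over 1.5 times in the genotype set alone include FTL (0.56), FTH1 (0.51), EGR1 (0.84), ARRDC4 (−0.38), KIF20A (−0.42) and NPLOC4 (−0.08).

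The next comparison set UFD1s-deficient cells against WT. The transcripts with the largest rises had at most 78 reads in any WT library. RORB, a nuclear receptor, had 0 reads in both WT libraries of the genotype set and 106 and 85 in deficient mock and GD, at least 33.7-fold and 27.1-fold higher against a floor of 3 counts per library (exact 95% lower limits 26.9 and 21.6). SOCS2, a cytokine signalling suppressor, went from 1 to 12 reads in mock (11.4-fold, 95% counting interval 1.69 to 489) and from 0 to 74 in GD (at least 23.6-fold, exact 95% lower limit 18.7). The ephrin receptor EPHA7 was higher by 5.25 on the log2 scale, the protease ADAMTS12 by 4.18, RAB39A by 4.11, TMEM74 by 3.35, DOCK10 by 3.24, NOD2 by 3.004 and the GABA receptor subunit GABRQ by 2.76 (SE 0.259, edgeR adjusted p = 0.002353). The largest fall was VPS9D1-AS1, from 931 to 21 reads in mock and from 741 to 17 in GD (log2 −5.52, SE 0.222, edgeR adjusted p = 5.654e-06), an antisense transcript whose strand the counts do not state. The kinase gene ALPK3 changed by −2.75 (SE 0.146, edgeR adjusted p = 2.61e-05), the transcription factors GBX2 and FOXF1 by −2.12 and −2.03, SPATA33 by −1.97, ZNF429 by −1.71, ZNF117 by −1.64 and the stem cell marker LGR5 by −1.55. ATG4C and ATG101, which act in autophagosome formation, changed by −3.06 and −2.31. Their stress-set WT mock libraries lay at 1.15 and 2.23 CPM (reads scaled to library size), near the 1.96 and 4.67 of deficient mock and below the 15.5 and 37.2 of genotype-set WT mock.

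Few members of the fixed lists changed with genotype. AARS (−0.77, integrated stress response), SPG7 (−0.89, mitochondrial stress), CDT1 (−0.84, DNA replication), LAMB1 (−0.67, extracellular matrix) and ATG101 fell, and EDEM1 (0.70, ER-associated degradation) rose. Camera called 0 of 26 lists, with unadjusted p in limma of 0.002273 for interferon and NF-kB, 0.0078 for extracellular matrix, 0.0117 for mitochondrial stress and 0.0166 for immediate early genes. Camera with an estimated correlation and fry also called 0, fry giving the immediate early genes an unadjusted p of 0.004502 and the apoptosis genes 0.0325. Adjusted over the list alone, extracellular matrix had 5 rises and 1 fall, autophagy 1 and 3, DNA replication 0 and 3, integrated stress response 0 and 2, respiratory chain 0 and 2, and each other list at most 1 in each direction. In the 4 libraries of the genotype set alone, camera called 4, with the integrated stress response and mitochondrial stress lists lower and the immediate early and extracellular matrix lists higher in deficient cells. Of the 81 lower calls, 80 could be placed on a chromosome of GRCh38.p14, 37 of them (46.3%) on chromosome 16, which holds 4.29% of tested transcripts, and 18 (22.5%) on chromosome 7, which holds 4.63%. From NOMO3 to URAHP on chromosome 16, 34 of 299 tested genes were called lower and 1, NOD2, higher, and the median log2 ratio of the stretch was −0.51 in mock and −0.51 in GD. VPS9D1-AS1, FOXF1, SPATA33, AARS, SPG7 and CDT1 lie in it, and ZNF117 and LAMB1 lie in stretches on chromosome 7. Chromosome 16 also holds SLC7A5 of the integrated stress response list and DNAJA3 and TRAP1 of the mitochondrial stress list. GARS and PSPH of the integrated stress response list lie on chromosome 7. These members were lower in deficient cells in mock and in GD. The lists were not tested without such genes, so how far the chromosomes account for the lower lists stays open.

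**Figure D2:**
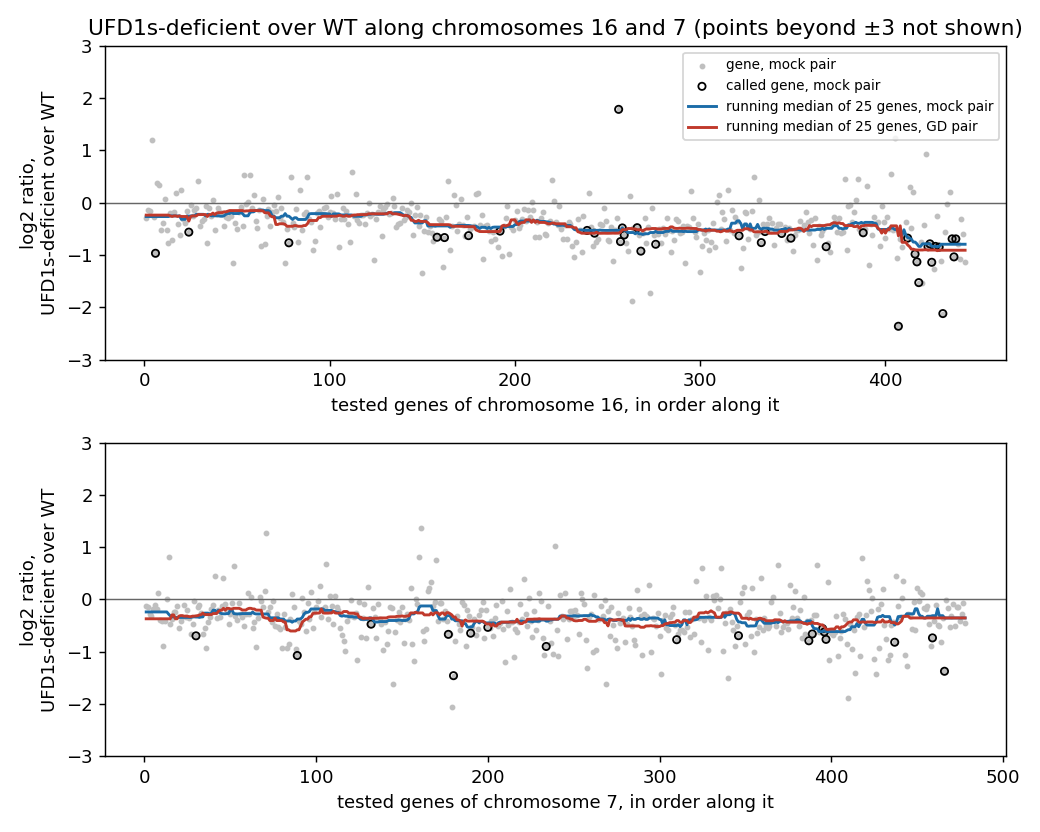
Log2 ratio of UFD1s-deficient over WT reads (y axis) for each tested gene in its order along chromosomes 16 and 7 (x axis), with grey points for the mock pair, black circles for called genes and lines for the running median of 25 genes in the mock pair (blue) and the GD pair (red). Both lines lie below 0 along all of chromosomes 16 and 7, and the stretch from NOMO3 to URAHP has a median of −0.51 in each pair.

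The test called 115 of 10368 transcripts, 34 higher and 81 lower, 54 of them at least 2-fold, and 1470 had an unadjusted p under 0.05. The result rests on 1 library per genotype and treatment from 1 deficient line, so the genotype and the line cannot be told apart. The spread used in this test also holds the difference in GD response between the 2 WT sets. The count was 5 without deficient mock and 5 without deficient GD, 1655 and 1938 without WT mock and WT GD of the stress set, and 1942 in the genotype set alone. It was 222 with DESeq2, 42 without the genes of the chromosome 16 stretch and 27 without those of the chromosome 16 and 7 stretches. The fits without stretches kept the genes of chromosomes 16 and 7 that lie outside the removed stretches. The excess of lower calls held with DESeq2 (71 higher and 151 lower). It was smaller in the genotype set alone (915 and 1027) and nearly gone without both stretches (13 and 14). The authors' deposited columns give deficient over WT separately for mock and GD, each from 1 library against 1. Their p-values are therefore not set beside the 115 calls. In these columns VPS9D1-AS1 had log2 ratios of −5.54 in mock and −5.50 in GD.

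Thapsigargin, the ER stress arm, was read in HEK293T from 1 library against 1 mock library, with no replicate check and no p-value, so its changes are those of these libraries. HSPA5 was 20.1-fold higher, from 13540 to 281566 reads (95% counting interval 19.8 to 20.5). XBP1 was 21.1-fold higher (15.6 to 29.2), HERPUD1 23.0-fold (14.9 to 37.5), DDIT3 51.1-fold (19.7 to 189) from 4 reads, and TRIB3 16.03-fold (14.5 to 17.8). The chemokine CXCL8 went from 8 to 687 reads (83.2-fold, 42.0 to 193.5), TNFRSF9 was 20.3-fold higher and SLC7A11-AS1 16.1-fold. A noncoding transcript of SAT1, the gene of a polyamine enzyme, was 18.5-fold higher. It need not follow the transcript that encodes the enzyme. KLHDC7B, with 0 reads in mock, was at least 36.8-fold higher (exact 95% lower limit 29.5). HSPA1B went from 21545 to 1671 reads, a log2 ratio of −3.73. TMEM37 (−3.31), the receptor NOTCH3 (−2.77), MYCN (−2.52), IFI44L (−2.51), RAB6C (−2.42), ARHGAP5-AS1 (−2.33), NYNRIN (−2.31), TRERF1 (−2.18) and PLEC (−2.14) were the other lowest. By list, 26 of 28 measured ER genes and 23 of 28 integrated stress response genes were at least 2-fold higher, with medians of 2.06 and 1.68. The median of 15 interferon and NF-kB genes was 0.94, with 7 at least 2-fold higher, and that of 20 immediate early genes 0.68, with 8. Each of these 4 medians lay at percentile 100 of 10000 random lists matched on expression. Heat shock genes had a median of −0.44 (percentile 0) with 3 of 12 at least 2-fold lower, G2 and M genes −0.40 (percentile 0.01), fatty acid synthesis −0.51 (percentile 0.18), and ribosomal proteins −0.02 (percentile 32.7). Small structural RNAs, the list for library quality, had a median of 0.48 (percentile 99.8) and histones 0.48 (percentile 100), while neuronal markers lay at −0.77 (percentile 0.12) and extracellular matrix genes at −0.38 (percentile 0.06). By the rule of at least 2-fold and 50 reads in the higher library, 733 of 9116 transcripts differed, 431 higher and 302 lower. With library totals alone the median of all transcripts moved from 0.01 to −0.10 and the split became 352 higher and 395 lower.

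Whether GD and TG change the same transcripts was asked within the stress set, over transcripts with 50 or more reads in any of its 3 libraries. In HEK293T, 148 transcripts were at least 2-fold higher in both and 78 lower in both, against 17.2 and 10.98 for independent lists and a mean of 1.15 and 0.35 in unchanged libraries simulated with the same shared mock. In opposite directions 14 changed, against 27.7 for independent lists. Of 744 transcripts past the rule in TG, 226 (30.4%, exact 95% interval 27.1 to 33.8) changed the same way in GD. Such intervals of a share, here and below, take transcripts as independent, which they are not. They hold no spread between repeats of a library. Across transcripts the ratios correlated at r = 0.473, but the simulated libraries gave r = 0.493. The covariance was 0.168 against 0.0480 in the simulation. With the GD ratio of genotype-set WT, which has a separate mock, r was 0.471 and 82 and 132 transcripts were higher and lower in both, against 9.75 and 15.1. In N2a, 401 were higher and 209 lower in both (99 and 48.8 for independent lists, 2.05 and 0.9 simulated) and 46 changed in opposite directions (140 for independent lists), 610 of 1906 (32%, exact 95% interval 29.9 to 34.2) changed the same way, r was 0.472 against a simulated 0.5001, and the covariance was 0.316 against 0.0516. In HEK293T the share with the separate mock was 29.2% (exact 95% interval 25.9 to 32.6). Most of the HEK293T excess thus does not need the shared mock, as far as this 1 further pair shows. In N2a the mock library could not be split. The simulation holds no real change and used the HEK293T dispersion, so part of the N2a excess may come from the shared mock.

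In N2a cells, 1465 of 9816 transcripts passed the same rule in GD, 810 higher and 655 lower, and 1871 of 10290 in TG, 1158 higher and 713 lower. The deposited table names transcripts by accession and does not pair them with gene names. In GD, NM_013675 went from 10 to 890 reads and NM_013624 from 10 to 657, and NM_007392 from 540 to 34 and NM_020274 from 496 to 37. In TG, NM_010493 went from 8 to 1551 reads and NM_001024932 from 2 to 632 (294-fold, 95% counting interval 81 to 2432), and NM_027975 from 1204 to 122 and NM_177303 from 479 to 54. These counts come from 1 library each. With library totals alone the TG median moved from −0.03 to 0.08 and the split became 1395 higher and 531 lower.

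Last, the GD response was compared between deficient and WT cells of the genotype set, without a test. The ratio was higher in deficient cells for CASP2 by 2.84, RTL9 by 2.74, FOXM1 by 2.70, SOCS2 by 2.63 and FOXE1 by 2.57 on the log2 scale, and lower for GOLM1 (−2.48), FOXA3 (−2.39), ZNF562 (−2.21), SPHK1 (−2.16) and MTMR14 (−2.14). All 10 had at most 104 reads in their highest library. ER chaperone genes had a median difference of 0.14 (percentile 99.99) and integrated stress response genes −0.19 (percentile 0.04), against 0.82 (percentile 100) and 0.15 (percentile 97.6) between the 2 WT sets. Other lists lay near an end of their matched random lists as well: extracellular matrix 0.20 (percentile 100), cholesterol 0.20 (percentile 99.97), fatty acid synthesis 0.21 (percentile 98.95), heat shock 0.11 (percentile 99.89), respiratory chain 0.08 (percentile 99.87) and fatty acid oxidation −0.20 (percentile 0.63). Between the WT sets these lay at 0.24, 0.23, −0.01, 0.32, −0.21 and −0.04. Of 10373 transcripts, 358 differed at least 2-fold, 196 higher and 162 lower. Over shared transcripts 275 of 9251 did, against 645 of 9292 between the WT sets, and the SD of the difference was 0.389 against 0.553. By that count and SD the response differed less between genotypes within the genotype set than between WT of the 2 sets. The WT difference also holds whatever sets the 2 sets apart, so it does not measure repeats within a set. With 200 reads required in the highest library, 18 transcripts differed at least 2-fold between genotypes.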

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

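Chosen only after the result was seen were the test of a gain in the WT libraries, the test of variation between repeats and the present form of the test of scaling.

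Among the 10 named transcripts with the largest difference in GD ratio between genotypes, 6 had opposite signs in WT and UFD1s-deficient cells of the genotype set and no WT ratio of the stress set that went against genotype-set WT. The difference was not tested, since there is 1 library per condition. Picking the largest differences favours opposite signs, so their number is no result in itself. Reads were few: FOXM1 had 0 and 16 in deficient mock and GD, and ZNF562 had 6 in deficient GD. CASP2 had 10 in WT GD and FOXA3 had 10 in deficient GD. With 200 reads required, 0 of the 10 passed. Deficient minus WT was 2.84 for CASP2 (−2.17 in WT, 0.67 in deficient cells), 2.70 for FOXM1 (−0.57 and 2.13) and 2.57 for FOXE1 (−1.61 and 0.96). It was −2.39 for FOXA3 (0.59 and −1.81), −2.21 for ZNF562 (0.40 and −1.81) and −2.14 for MTMR14 (1.30 and −0.84). Stress-set WT had ratios of −2.02 for CASP2 and 0.84 for MTMR14, but only −0.16 for FOXE1 and 0.04 for FOXA3, and none was measured for FOXM1 and ZNF562. SOCS2 and GOLM1, also among the 10, had opposite signs too, but their stress-set WT ratio went against that of genotype-set WT.

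Lower calls in UFD1s-deficient cells gathered on chromosome 16. GC content bias is argued against, because genes of matched GC content on other chromosomes lay 0.528 above the stretch from NOMO3 to URAHP. A gain in the genotype-set WT libraries is argued against as well: over stress-set WT mock, the stretch lay −0.00207 from GC-matched genes elsewhere. That test replaced an earlier one on the raw ratio, 0.243, which fell between its bounds and decided nothing. A candidate explanation is fewer copies of the stretch in the deficient line: with the stretch set on the mock pair, its 264 uncalled genes had a GD median of −0.46, and 90.5% lay below 0. A running-median cut of −0.3 bounds the stretches, but lower values reach beyond them. The median log2 genotype difference was −0.45 over all of chromosome 16 and −0.37 over all of chromosome 7. On the other chromosomes it ran from −0.08 to 0.11. Stretches on chromosome 7 had medians from −0.38 to −0.46 in mock. A gain in WT was not tested there and stays open for the stretch from DLX5 to KMT2E, where genotype-set WT mock lay 0.50 and deficient mock 0.02 above stress-set WT mock. In the other 3 stretches WT lay at 0.06, 0.08 and −0.16 and deficient cells at −0.35, −0.39 and −0.60. Whether UFD1s loss, the history of a line or both underlie either pattern stays open, with 1 line per genotype.

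The GD rise of ER chaperone genes was slightly larger in deficient cells, with a median difference of 0.14, and was not particular to them, since the extracellular matrix and cholesterol lists each differed by 0.20. A factor per library moves all transcripts alike and cannot set the list apart, which lay 0.152 above the median of all transcripts. That median was −0.02, so the test restates the list's 0.14, which was known when its form was chosen. It adds no separate evidence. That test replaced an earlier one with library totals alone (0.157), a switch that moved all transcripts alike and so decided nothing. Variation between repeats may account for it: the same median differed by 0.82 between the 2 WT sets. That value crosses 2 sets, while the 0.14 lies within the genotype set, so the comparison cannot decide this. An effect of UFD1s loss stays open and untested.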

How the results depend on the processing

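Chosen after seeing the data were the fits in the genotype set alone for GD and the lists, without chromosome stretches, on symbols with 1 transcript, and fry with trended variance. GD called 2164 transcripts, with 1976 to 2279 under other size factors, filters, DESeq2 and limma-trend. Changes beyond 1.5 times were 23 with treatment only, 490 in the 4 WT libraries, 4040 in the genotype set, 607 on symbols with 1 transcript (2861 tested, so fewer genes), 422 at 2-fold, and 494 to 4039 leaving out 1 library. Genotype called 115, with 82 to 119 under other size factors, filters and limma-trend, but 222 with DESeq2, 1942 in the genotype set, 42 without the chromosome 16 stretch, 27 without the chromosome 16 and 7 stretches, 15 on symbols with 1 transcript, 54 at 2-fold, and 5 to 1938 leaving out 1 library. The filter alternative of 1 count removed no tested transcript and is void. At 20 counts, 200 counts, 1.5-fold and 3-fold, TG gave 1128, 402, 2044 and 219 transcripts, N2a GD 2338, 729, 3393 and 473, N2a TG 3005, 889, 4235 and 670, and the response by genotype 722, 18, 1310 and 60, with 154 at a prior count of 20. The N2a share of TG changes seen in GD was 26.0% at a prior count of 20 and 34.4% at 1. The HEK293T share ran from 27.3% at a prior count of 20 to 31.7% at 20 counts. Camera called 11 lists in GD, camera with an estimated correlation 0, fry 2, and fry with trended variance 5, of which immediate early genes and hypoxia are outside the 11; for genotype, 0 became 4 in the genotype set. Beyond thresholds and fewer libraries or genes, the cause was not tested. The balance of GD calls turned to 1147 higher and 1058 lower with RLE factors, 1018 and 958 with DESeq2 and 14 and 9 with treatment only, and that of TG to 352 and 395 with library totals. Genotype calls, 34 higher and 81 lower, came nearer to even in the genotype set (915 and 1027). Without the chromosome 16 and 7 stretches they were 13 and 14. No named gene reversed direction while called: of 1533 values for named genes in GD 1323 stayed on their side of the threshold and 210 lost the call, and of 419 for genotype 341 stayed, 75 lost it and 3 gained it. These totals include the void filter alternative. In every setting that tested them, 12 of 94 named genes in GD and 3 of 27 for genotype stayed on their side. With treatment as the only term, 82 of the 94 in GD lost the call. HEK293T against N2a was not run, and settings for values other than counts did not apply. The labels give no replicate numbers that pair libraries, and pairing in GD comes from the set and genotype terms. Depth limits transcripts under 50 reads, where 1 library decides a ratio.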

Other observations

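The choice of genes moving in opposite directions in GD and TG was made after the values were seen, and the tests on snoRNA hosts and splits were set before.

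In the HEK293T stress set, 14 transcripts changed at least 2-fold in opposite directions in GD and TG, fewer than the 27.7 for independent lists. Heat shock genes were among them. HSPA6, an inducible HSP70, had 6 reads in mock, 1082 in GD and 0 in TG. Its relative HSPA1A had 42, 116 and 6 reads, and the co-chaperone DNAJB1 had 3319, 6190 and 1706. DNAJB1 did not repeat this in the genotype set, where its GD log2 ratio was −1.18 in WT and −0.91 in deficient cells, and HSPA6 and HSPA1A have no ratio there. ARRDC4, a glucose-responsive arrestin, went the other way, with 971, 298 and 2506 reads, as did the chemokine CCL2 with 37, 0 and 180. The others were LGI1, CGA, FAM222A, HIST1H2AI, PTGER2 and PRKAG1, lower in GD, and CTDSPL, UNC13D and SCARA5, higher in GD. The 5 lower in GD with a ratio in the genotype set fell in WT there too, with ratios in WT and deficient cells of −1.17 and −0.20 for CCL2, −0.68 and −0.07 for ARRDC4, −0.64 and −0.94 for PTGER2, −0.62 and 0.05 for HIST1H2AI and −0.46 and 0.10 for FAM222A. CTDSPL, UNC13D and SCARA5 did not repeat their 2-fold rise there, with ratios in WT and deficient cells of −0.0024 and 0.16 for CTDSPL, −0.14 and −0.26 for UNC13D and −0.20 and −0.96 for SCARA5.

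Transcripts that host small nucleolar RNAs rose in GD beyond the members of the fixed list, a pattern noticed in these data. Of 8 other hosts, 5 were called higher (SNHG8, SNHG17, SNHG15, SNHG6 and SNHG12) and 0 lower, with a median log2 change of 0.72, at percentile 100 of matched lists. A general rise of noncoding RNA is argued against, since the hosts lay 0.662 above the median of 894 other noncoding transcripts. The same hosts had a median of 1.14 in TG, in line with a stress response shared by both treatments, which stays a hypothesis from 1 TG library.

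The 6 mock and GD libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2164 transcripts, 1 of the 10 splits called as many, the real one itself, and the highest of the others called 0. Each other split leaves any GD effect in its residual spread, so few calls were likely in advance. The 0 is therefore no measure of chance and gives no support.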
